A study of Mus musculus with 14 samples.

How the data were processed

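The samples were gastric organoids grown from mouse stomach, profiled by CUT&Tag, in which an antibody directs a transposase to the chromatin around a protein and the tagged DNA is sequenced. TP organoids were Trp53-null with guide RNAs against Pten, and TPA organoids carried additional guide RNAs against Arid1a. BRD9 was profiled in 3 TP and 3 TPA samples. ARID1A was profiled in 2 TP and 2 TPA samples, and in 2 further TP samples, labelled premalignant like the BRD9 samples, for which a single list pooled over both was used. The 2 IgG samples were not analysed here, so no background list enters any comparison. In all, 11 peak lists from the 14 samples were used.

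The tools named in the submitters' processing notes are fastp, Bowtie2, SAMtools, Picard, deepTools, MACS2, ChIPseeker and DESeq2, without versions, and the build is mm10. The deposited lists have the column layout that MACS2 writes for narrow peaks and were made per sample, except the pooled list. The fold enrichment of each peak over the caller's background is the authors' own value, a ratio as deposited. The −log10 p and −log10 q of each peak are likewise the authors' deposited values. The smallest deposited −log10 q was 5.01 in the BRD9 lists and 5.16 in the pooled ARID1A list, and 2.00 in the ARID1A lists of the later samples, so the authors' thresholds differed between these sets. Folds and q values were used to describe, rank or filter peaks within a list, since a fold in one list is not on the scale of another. The lists hold no reads, so the depth of each library is unknown. A longer list can come from more reads, a better antibody reaction or more background.

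Peaks on chromosomes 1 to 19, X and Y were kept. For each antibody, peaks of the TP and TPA libraries were merged into union regions where they shared at least 1 bp, and a region was called in a library that had a peak in it. Regions called in every TP library and in no TPA library are referred to as lost, and the reverse as gained. These words describe calls, not amounts of protein. Gene names, identifiers and spans came from the RefSeq annotation of GRCm38.p6, the assembly that mm10 stands for, with 21883 protein-coding genes. That table has no strand and no exons, so promoters could not be placed as planned. In their place, a peak was assigned to a gene when it lay within 1 kb of either end of the gene's span, called a gene-end peak below. Whether a peak is exonic, intronic or in a UTR was not determined. Without a genome sequence, the planned motif search was not run.

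Numbers of peaks and shares of gene-end peaks were compared between genotypes with a two-sided exact permutation test over libraries. With 3 against 3 libraries its smallest p is 0.10 and with 2 against 2 it is 0.333, so neither design can reach 0.05. The labels do not say that replicates came from separate cultures. The p-values therefore measure the spread between these samples, which may be technical. The background of gene-end peaks was measured after random circular shifts of each list along the chromosomes. For co-occupancy, the pooled ARID1A list was shifted 1000 times, and the other lists 100 times. Intervals of shares are exact binomial (Clopper-Pearson) 95% intervals. They cover counting error over regions only.

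A total of 29 gene lists was fixed before the data were examined, as were the groups, tests, alternatives and the rule for named genes. Of their genes, 1057 were found in the annotation and 5 were not. For each list, the mean number of TPA minus TP libraries with a gene-end peak was compared with 100000 random lists of the same size, matched on the number of calling libraries, in a two-sided permutation test over genes with Benjamini-Hochberg adjustment over the lists. Genes are not replicates, so this test describes these libraries. The rule named the targeted genes, the 12 lost and 12 gained BRD9 genes and the 10 lost and 10 gained ARID1A genes with the highest fold ranks within their lists, all mucin and SWI/SNF genes, up to 4 genes of each other list, and the 10 genes with the highest ranks for both proteins in TP. Predicted genes were passed over.

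Retention of BRD9 was computed over regions called in all 3 TP libraries, split by an overlap with the pooled ARID1A list. The edges of these regions were merged from TP and TPA peaks. A TPA peak can thus widen a kept region, which then meets an ARID1A peak more easily, so the split is not fully independent of retention. A Mantel-Haenszel odds ratio over 10 bins of TP fold rank held peak strength in part. On simulated data, all 200 planted lost and 100 planted gained regions were found among 28834 union regions of the BRD9 comparison. The simulated peaks had the exact edges of these regions, and no other region met the rule. This checks the counting, and not how well such regions are recovered from real lists. Over 21883 genes with calls dealt at random to the BRD9 libraries, 2.50% of 1160 list tests gave p below 0.05, and a planted list was found in 20 of 20 runs. Calls were dealt to each gene alone, with equal chance per library. Peaks shared by neighbouring genes, unequal list lengths and the ARID1A lists were therefore not simulated. For BRD9 retention, the odds ratio averaged 3.02 for a true value of 3 over 15000 simulated regions, and its 95% interval held the true value in 93% of 200 runs.

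The alternatives were a stricter threshold (−log10 q of at least 10 for BRD9 and the pooled list and 5 for the other ARID1A lists), lists of equal length (the 13236 strongest peaks by q for BRD9 and 30066 for ARID1A), 500 bp windows around summits, windows of 3 kb, gene spans with 10 kb on each side, a replicate block, other definitions of ARID1A and of TP regions, and leaving out each library. The computations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, and matplotlib 3.10.9 for plots.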

Results

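The study compared gastric organoids of the TP genotype, in which Trp53 was deleted and Pten targeted, with TPA organoids, in which Arid1a was targeted as well. ARID1A is a DNA-binding subunit of the canonical SWI/SNF (BAF) chromatin remodelling complex, and BRD9 is a bromodomain subunit of the non-canonical form of that complex. The series title places the question in the production and secretion of mucin in signet ring cell carcinoma. BRD9 peaks were available for 3 TP and 3 TPA libraries and ARID1A peaks for 2 TP and 2 TPA libraries, with a further ARID1A list pooled over 2 TP samples. BRD9 lists held 18565 to 20632 peaks in TP and 13236 to 25797 in TPA. ARID1A lists held 32757 and 30066 peaks in TP, 59049 and 110176 in TPA, and 27642 in the pooled list. Read depth is unknown for every library.

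The targeted genes were examined first. At the end of Arid1a itself (gene 93760, chromosome 4, 133679008 to 133756769), an ARID1A peak spanning 133756476 to 133757560 was called in both TP and both TPA libraries, and a BRD9 peak in 3 of 3 TP and 2 of 3 TPA libraries. At Brd9 (gene 105246, chromosome 13, 73937801 to 73960895), ARID1A was called in 2 of 2 TP and 0 of 2 TPA libraries, and BRD9 in all 6 libraries. Pten, which encodes a lipid phosphatase that opposes PI3K signalling, had BRD9 in all 6 libraries and ARID1A in 2 TP and 1 TPA libraries. Trp53, which encodes the p53 tumour suppressor, had both proteins called in every library. A peak near a gene's end does not show whether the edited protein was lost, so these calls do not check the genotypes.

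ARID1A occupancy in TP was reproducible and lay often at genes, whereas the TPA libraries held more peaks that lay elsewhere and differed from each other. Of the peaks of TP replicate 1, 77.8% overlapped a peak of replicate 2, against 10.9% for the corresponding TPA libraries, where randomly shifted peaks gave 4.19%. Gene-end peaks made up 28.3% ± 1.04 of the TP lists (SD, n = 2) and 9.06% ± 1.85 of the TPA lists (SD, n = 2), with shifted peaks between 3.82% and 4.10%. The mean number of peaks was 31412 ± 1903 in TP (SD, n = 2) and 84613 ± 36152 in TPA (SD, n = 2). Both differences had p = 0.333 in the two-sided exact permutation test, the smallest value that 2 against 2 libraries allow, so neither can reach 0.05. Within the TP lists, the gene-end share was 34.3% and 36.6% in the highest of 4 equal classes of fold enrichment and 21.5% and 22.8% in the lowest class. In the TPA lists the order was the opposite, with 6.93% and 5.85% in the highest class and 12.9% and 9.12% in the lowest.

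**Figure D1:**
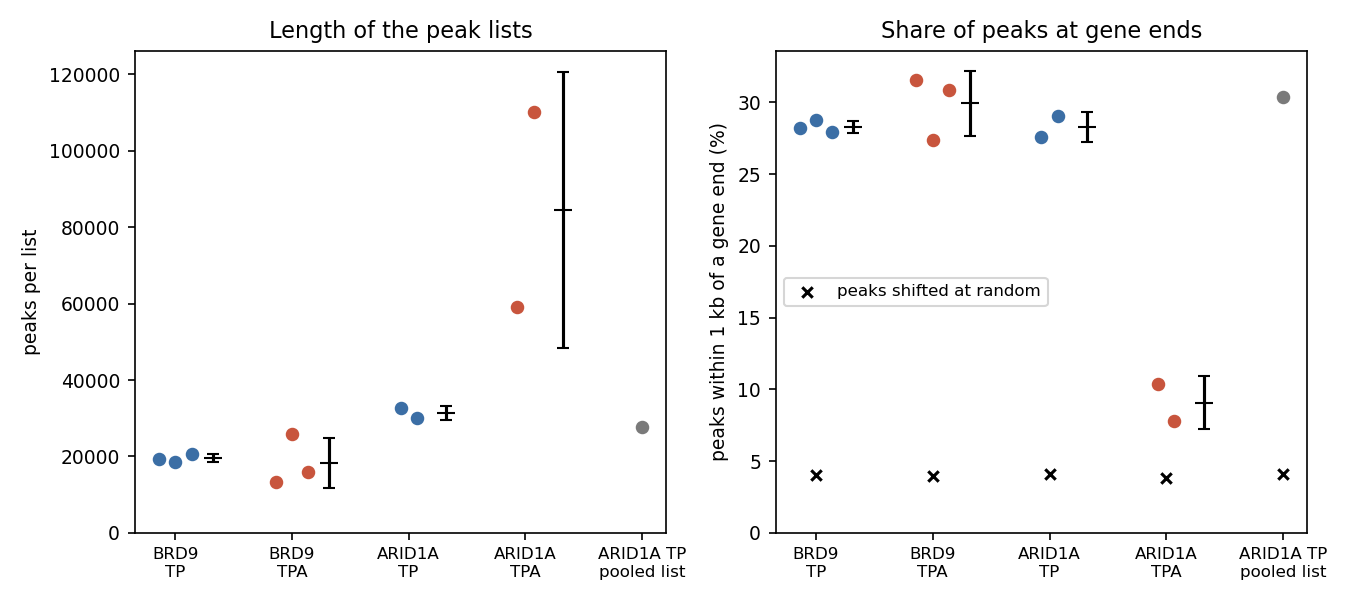
Number of peaks per list (left) and percent of peaks within 1 kb of a gene end (right) for each library (points), with the mean and SD of each replicated group (black bars) and the share after random shifts (crosses, mean per group). The ARID1A TPA lists hold 59049 and 110176 peaks, the most of all lists, and have the lowest gene-end shares, 10.4% and 7.76%.

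**Figure D2:**
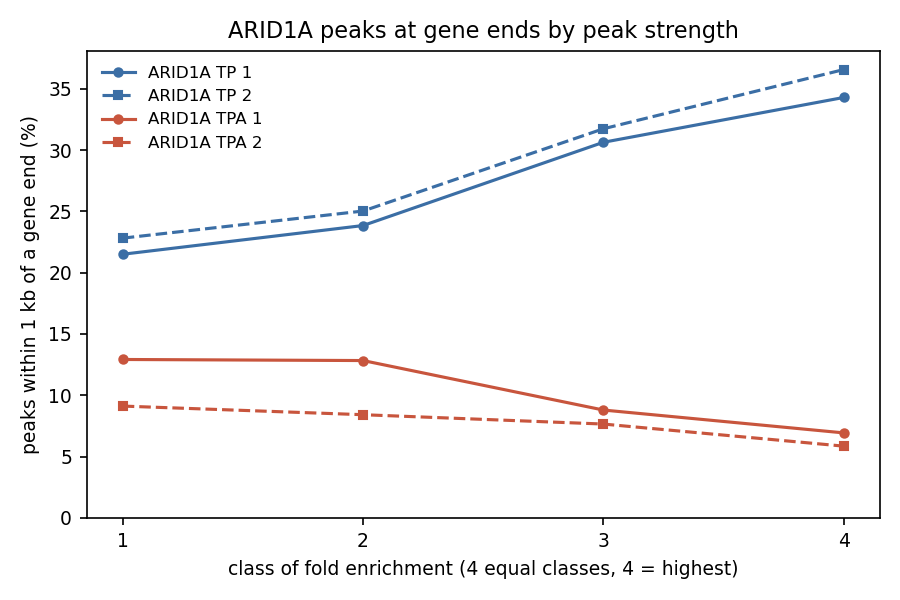
Percent of ARID1A peaks within 1 kb of a gene end, in 4 equal classes of each list ranked by the authors' fold enrichment (class 4 is the highest). Each line is 1 library. The share is higher in the highest class than in the lowest in both TP libraries, and lower in both TPA libraries.

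Of the 25192 ARID1A regions called in both TP libraries, 12982 (51.5%) had no peak in either TPA library, 8609 (34.2%) had one in a single TPA library and 3601 (14.3%) in both. BRD9 lay more often at the regions still called: it was present in all TP libraries at 33.9% of the lost regions, 60.3% of those called in a single TPA library and 82.3% of those called in both. The gene-end share went the same way, with 26.5%, 35.9% and 39.7%. These regions were also wider, with median widths of 652, 949 and 1247 bp, and a wider region meets a peak more easily. By contrast, 2961 regions were called in both TPA libraries and in no TP library, of which 10.1% lay at gene ends and 4.32% carried BRD9 in all TP libraries. The lost and gained regions together numbered 15943, against at most 1139 for the other splits of the 4 libraries, and the 3 possible splits are too few for a share under 0.05. The gained number depended on the libraries and list lengths, with 99524 regions without TPA replicate 1, 50515 without TPA replicate 2 and 404 with lists of equal length.

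At the level of genes, 2333 of 21883 genes had a gene-end ARID1A peak in both TP and no TPA library, 492 in both TPA and no TP library, and 2492 in all 4 libraries. With lists of equal length, 4561 genes were lost and 67 gained. The lost genes with the highest fold ranks included Immt, a scaffold of mitochondrial cristae (gene 76614, peak on chromosome 6 from 71831131 to 71831892, inside the gene near its end, TP fold 12.4 to 13.3), and Pgk1, a glycolytic kinase (gene 18655, peak on chromosome X from 106186529 to 106187173, across the gene's end, TP fold 10.8 to 11.5). Dynlt1b, a dynein light chain, Anapc4, a subunit of the anaphase-promoting complex, Kbtbd7, Cbwd1, Cep43 and Zbtb10 were also among them, as were Azi2 and Zcwpw2, which share a region. The gained genes included Hif1a, the oxygen-regulated transcription factor subunit, Pou5f1, a pluripotency factor, Slc7a9, an amino acid transporter subunit, Mbl2, a lectin of the complement pathway, and Alg10b, P2ry14, Basp1, Wdr48, Cped1 and Tgfb1i1. A single region was called in all the calling libraries at 99.3% of the lost genes and at 134 (27.2%) of the gained genes. The remaining gained genes had peaks at different places in the TPA libraries, and these include 6 of the 10 gained genes named here: Hif1a, Pou5f1, Slc7a9, Mbl2, Alg10b and Cped1. For a gene called in 2 of the 4 libraries, chance parts the calls fully by genotype in 1 of 3 cases.

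Among the 29 gene lists, Hox genes, the homeobox genes that set position along the body axis, were the only list past the threshold for ARID1A. None of the 39 Hox genes had a gene-end ARID1A peak in a TP library, while 10 (25.6%) had one in each TPA library, 16 in either and 4 in both, namely Hoxa5, Hoxa6, Hoxc9 and Hoxd10 (adjusted p = 0.00174, permutation test over genes with Benjamini-Hochberg adjustment). These 10 genes stood for 9 peaks in each TPA library, since neighbours such as Hoxa5 and Hoxa6 can share a peak. Over the alternatives the adjusted p of this list ranged from 0.00029, the smallest the permutations can give, to 0.417, and the call ended without TPA replicate 1 (adjusted p = 0.417), without TPA replicate 2 (0.193) and with whole gene spans (0.328). No list passed without either TPA library, 4 lists passed without TP replicate 1, among them cell cycle, ribosomal and exocytosis genes at adjusted p = 0.0371 each, and with whole gene spans the ribosomal proteins passed instead (adjusted p = 0.00899).

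The other lists did not pass for ARID1A, and 3 lists including Hox genes had an unadjusted p under 0.05. Gastric mucous cell markers had a gene-end peak at 14.8% of 27 genes in TP and 24.1% ± 13.1 in TPA (SD, n = 2, unadjusted p = 0.0151 and adjusted p = 0.219 in the permutation test over genes). TPA replicate 1 stood at 14.8%, like both TP libraries, and TPA replicate 2, the longest list, at 33.3%. In this list, 7 genes were called in more TPA libraries, such as Tff2 and Gkn3, secreted products of the gastric mucosa, and 3 in more TP libraries, such as Capn8 and Cd44. Several lists of other lineages were also called more often in TPA. Immune cell markers stood at 12.5% in TP and 26.6% in TPA, and fibroblast and endothelial markers at 8% and 20%. Neuronal genes, a silent control list, stood at 13.2% and 20.6%, while intestinal lineage markers were equal at 16.7%. AP-1 and immediate early genes had one at 85.7% of 28 genes in TP and 75% ± 5.05 in TPA (SD, n = 2; unadjusted p = 0.0305, adjusted p = 0.295, permutation over genes), with 5 genes called in more TP libraries, such as Ier5 and Nr4a1, and 0 in more TPA libraries. Of the 49 cell cycle and E2F target genes, 33 were called in more TP than TPA libraries and 4 in more TPA libraries, among the former Rb1, Rbl2, Cdc20 and Mcm3. Of the 57 ribosomal protein genes, 31 were called in more TP and 2 in more TPA libraries. Gene-end calls were fewer in TPA over all genes (9509 ± 148 genes in TP and 6971 ± 1396 in TPA, SD, n = 2 each), and against matched genes the adjusted p of these lists was 0.771 and 0.431 in the permutation test. Of the 31 SWI/SNF subunit genes, 18 were called in more TP libraries, including Brd9, Smarcb1, Actb and Bcl11b (2 of 2 TP and 0 of 2 TPA libraries each), and 3 in more TPA libraries, Smarcd3, Dpf1 and Ss18 (adjusted p = 0.771, permutation over genes). Among 13 mucin genes, Muc1, a membrane mucin, had ARID1A in 2 TP and 1 TPA libraries and Muc5ac, the main secreted mucin of gastric pit cells, in 1 and 1. Muc6, Muc5b and Muc3a were each called in 1 TPA library alone, and Muc15 in 1 TP library alone. The adjusted p of the mucin list was 1.

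In TP organoids, most BRD9 regions overlapped ARID1A peaks. Of the 15207 BRD9 regions called in all 3 TP libraries, 12926 (85.0%, 95% interval 84.4 to 85.6) overlapped the pooled ARID1A list, against a mean of 1.62% and a maximum of 5.08% over 1000 random shifts. The ARID1A lists of TPA replicates 1 and 2 overlapped 37.0% and 43.3% of these regions, against 2.96% and 5.45% after shifts. An excess over shifts thus also arose where Arid1a was targeted, so it does not by itself show ARID1A binding. The BRD9 regions with ARID1A lay at gene ends more often (33.7%) than those without (4.95%). In the other direction, 57.3% to 61.4% of the 25192 ARID1A regions overlapped a peak of a given BRD9 TP library. Genes with gene-end peaks of both proteins in all their TP libraries numbered 5064, out of 5174 with BRD9 and 8735 with ARID1A. The gene with the highest ranks for both was Lars2, which encodes mitochondrial leucyl-tRNA synthetase (gene 102436, BRD9 region on chromosome 9 from 123461792 to 123462271, inside the gene near its end, BRD9 fold 39.7 to 40.7). Immt, Fmo3, a flavin monooxygenase, Fxr2, Tbl2, Inpp5f, Coa7, Csnk1g2 and the neighbours Ccdc191 and Qtrt2 followed. The Lars2 peak was not particular to a protein or genotype: it was called in all TPA libraries of both antibodies and was the strongest peak of 8 of the 11 lists, ARID1A TPA replicate 2 among them.

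**Figure D3:**
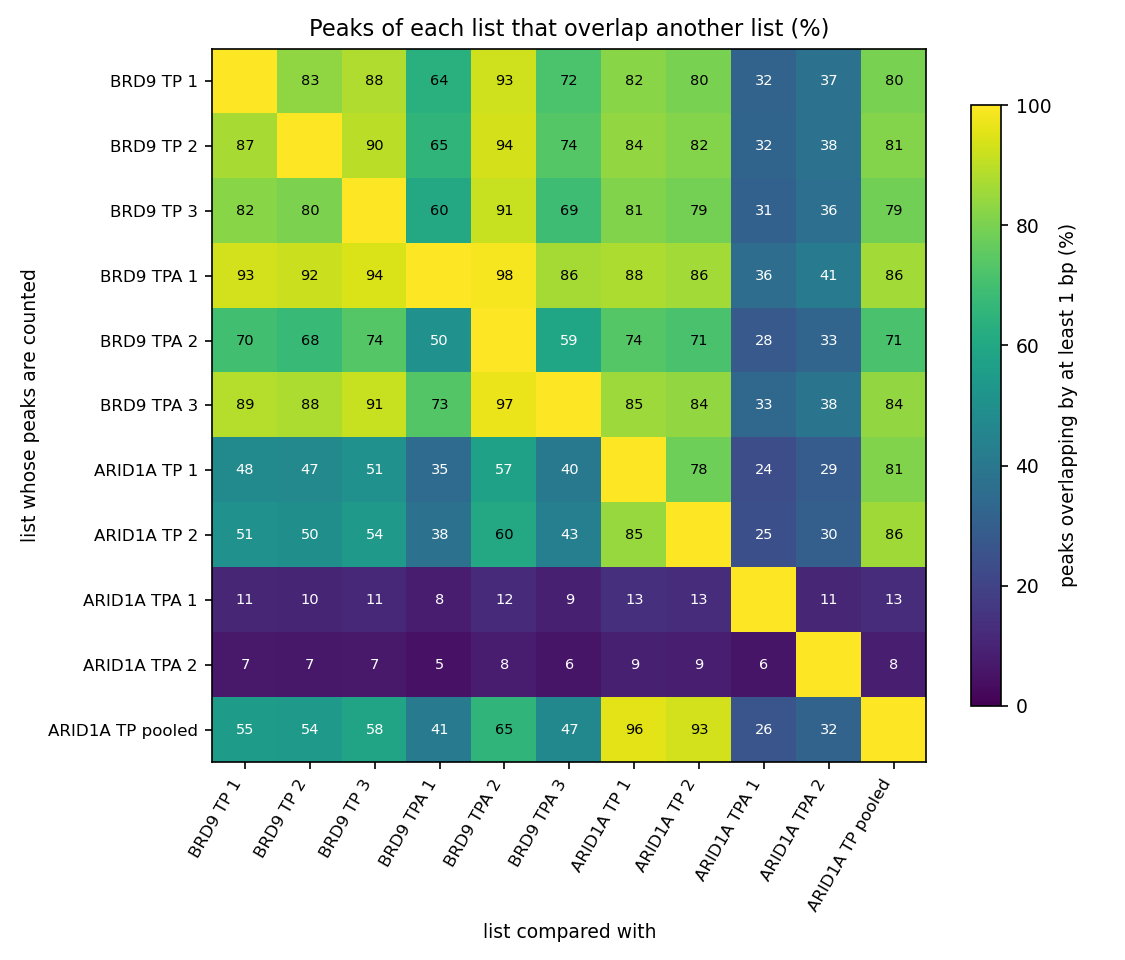
Percent of the peaks of each list (vertical axis) that overlap each other list (horizontal axis) by at least 1 bp, for the 11 lists. BRD9 lists and TP ARID1A lists overlap one another widely, while 10.9% of the peaks of ARID1A TPA replicate 1 overlap replicate 2.

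Few BRD9 regions were called in every library of one genotype and in none of the other. Of 28834 union regions, 10698 (37.1%) were called in all 6 libraries, 219 were lost in TPA and 55 gained. The rest were called in other combinations of libraries. ARID1A lay at 90.2% of the regions called in all libraries, 54.3% (47.5 to 61.1) of the lost and 36.4% (23.8 to 50.4) of the gained regions, with 95% intervals in parentheses. With lists of equal length, these shares were 91.5%, 65.9% (58.9 to 72.3) and 68.1% (59.8 to 75.6), so the lost regions no longer lay above the gained ones. At the deposited lengths, median widths were 753.5, 487 and 472 bp, and a wider region meets a peak more easily. Regions called in 2 TP and 1 TPA libraries carried ARID1A at 64.9%, and those in 1 TP and 2 TPA libraries at 62.9%. Gene ends held 32.4% of the shared, 11.4% (7.53 to 16.4) of the lost and 29.1% (17.6 to 42.9) of the gained regions. Lists held 19488 ± 1051 peaks in TP and 18324 ± 6611 in TPA (SD, n = 3 each; difference −1164, two-sided exact permutation p = 0.80), and the gene-end share was 28.3% ± 0.416 and 29.9% ± 2.25 (SD, n = 3 each; exact permutation p = 0.40). The difference in gene-end share was 1.62 percentage points (TPA minus TP), 0.80 without TPA replicate 1, 2.90 without TPA replicate 2 and 2.79 with lists of equal length. The differences over all libraries were smaller than the SD of the TPA libraries, and the exact permutation test with 3 against 3 libraries cannot go below p = 0.10.

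The numbers of lost and gained regions depended on the libraries compared. The other splits of the 6 libraries gave up to 661 such regions against 274 for the genotypes, and the 10 splits are too few for a share under 0.05. Without TPA replicate 2, the longest list, 1683 BRD9 regions were lost, and without TP replicates 1, 2 and 3 the number was 404, 466 and 355. The gained number was 459 without TPA replicate 1, 244 without TPA replicate 3, and 94, 86 and 129 without TP replicates 1, 2 and 3. A rule over fewer libraries is looser, which raises all these counts. The difference in peak number was 1380 without TPA replicate 1, 28.2 without TPA replicate 3 and −4900 without TPA replicate 2. With lists of equal length, 205 regions were lost and 144 gained. Together these were 349, against at most 195 for the other splits, a comparison chosen after seeing the data.

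The lost and gained BRD9 regions lay at few genes: 24 genes had a gene-end peak in 3 of 3 TP and 0 of 3 TPA libraries, 15 the reverse, and 4058 in all 6 libraries. With lists of equal length the balance was the opposite, with 13 genes lost and 72 gained. For a gene called in 3 of the 6 libraries, chance parts the calls fully by genotype in 1 of 10 cases. Lost genes included Atp8b3, a phospholipid flippase (gene 67331, peak on chromosome 10 from 80538651 to 80539365, TP fold 6.31 to 7.13), Plcd3, a phospholipase C that acts in calcium signalling (gene 72469, peak on chromosome 11 from 103102246 to 103103289, TP fold 5.38 to 6.50), Runx2, an osteoblast transcription factor, and Pnpla3, a lipid droplet protein. Ncoa5, Gnpda1, Fkbp1a, Cnpy2, Extl1, Stac2 and the neighbours Pcsk7 and Rnf214 completed the 12 with the highest ranks. Gained genes included Ogt, the enzyme that attaches O-linked GlcNAc to proteins (gene 108155, peak on chromosome X from 101639876 to 101640190, TPA fold 7.34 to 9.99), Cbl, a ubiquitin ligase for receptor tyrosine kinases (gene 12402, peak on chromosome 9 from 44233993 to 44234415, TPA fold 6.28 to 9.0), Rps3, a ribosomal protein, Selenot, a selenoprotein of the endoplasmic reticulum, and Nsun3, Ppig, Frk, Ceacam16, Pip4p2, Zmat5, Adgrb2 and Paip1. Of these 24 genes, 4 kept the full separation with lists of equal length, Atp8b3, Plcd3, Ogt and Cbl, and 8 with the stricter threshold. Of the 4, Plcd3 showed no difference between the genotypes with windows of 3 kb or with gene spans and 10 kb. Cbl showed none with gene spans, while Atp8b3 and Ogt kept the separation in both settings.

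None of the 29 gene lists passed for BRD9 in the permutation test with Benjamini-Hochberg adjustment, and 2 had an unadjusted p under 0.05. Hox genes had a BRD9 gene-end peak at 10.3% ± 2.56 of 39 genes in TP and 5.98% ± 1.48 in TPA (SD, n = 3 each; unadjusted permutation p = 0.0129, adjusted p = 0.374). Hoxa5 and Hoxa6 were called in 2 TP and 0 TPA libraries and Hoxa1 in 2 and 1. Epithelial junction and polarity genes had one at 58.9% ± 3.55 of 43 genes in TP and 51.2% ± 8.39 in TPA (SD, n = 3 each; unadjusted permutation p = 0.0379, adjusted p = 0.549). In that list, 9 genes were called in more TP libraries, including Cldn3, a tight junction claudin (3 of 3 TP and 0 of 3 TPA), and Cldn23 (3 and 2), and 1 in more TPA libraries. Among the SWI/SNF genes, Smarcd1 (2 TP and 0 TPA libraries), Arid2 (3 and 1) and Ss18l1 (3 and 1) stood against Bcl7a (0 and 2), with 45.2% ± 21.2 of 31 genes called in TPA and 52.7% ± 3.72 in TP (SD, n = 3 each; adjusted p = 1, permutation). Muc1 was the mucin gene with BRD9, in 3 TP and 2 TPA libraries, and the other mucin genes had none. Of the 65 calcium signalling genes, 14 were called in more TP libraries, such as Plcd3, Camk1d and P2rx4, and 4 in more TPA libraries (adjusted p = 0.881, permutation). Exocytosis and SNARE genes were called at 36.7% ± 0.825 in TP and 35.2% ± 8.12 in TPA (SD, n = 3 each; adjusted p = 1, permutation). Single genes of other lists with 3 TP and 0 TPA libraries were Mex3a, an RNA-binding protein of intestinal stem cells, and Wwc1, a Hippo pathway scaffold. Without TPA replicate 2, the lowest adjusted p over the lists was 1, and over all alternatives it ranged from 0.0821 to 1.

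BRD9 regions that carried ARID1A in TP were called more often in TPA than those without it. In TPA replicates 1, 2 and 3, a BRD9 peak remained at 79.5%, 98.8% and 86.7% of the 12926 regions with ARID1A and at 54.8%, 95% and 65.8% of the 2281 regions without it. The mean difference was 16.5 percentage points ± 11.2 (SD, n = 3), positive in 3 of 3 libraries, with a two-sided exact sign-flip permutation p of 0.25, the smallest that 3 libraries allow. With TP fold rank held in 10 bins, the odds ratios were 2.97 (2.70 to 3.27), 3.6 (2.82 to 4.60) and 3.06 (2.76 to 3.39), with 95% intervals over regions. In the lowest bin of fold enrichment, TPA replicate 1 kept 68.5% of the regions with ARID1A and 46.6% of those without, and in the highest bin 94.7% and 81.8%. The difference also arose within TP: among regions called in the other TP libraries, those with ARID1A were called in the TP library left out 8.79 percentage points ± 4.15 more often (SD, n = 3), with odds ratios of 1.95, 2.87 and 2.29. This comparison inside TP was chosen after seeing the data.

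**Figure D4:**
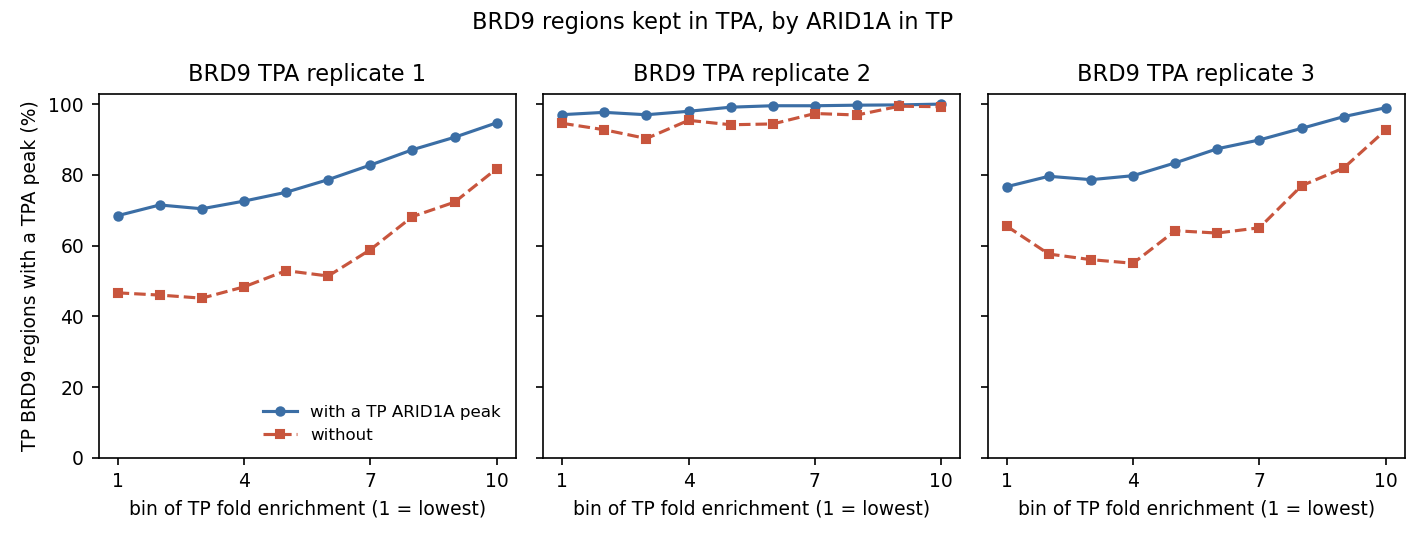
Percent of BRD9 regions of all 3 TP libraries that also have a BRD9 peak in each TPA library, by bin of TP fold enrichment (bin 1 is the lowest of 10), for regions with (circles) and without (squares) a peak of the pooled TP ARID1A list. Regions with ARID1A lie higher in every bin of all 3 TPA libraries.

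The ARID1A lists of the later samples were compared with the pooled list of the premalignant samples. Of its 27642 peaks, 96.1% (95.8 to 96.3) and 93.2% (92.9 to 93.5) overlapped the TP libraries, and 26.2% (25.7 to 26.7) and 31.9% (31.3 to 32.4) the TPA libraries, with 95% intervals. The difference of the means was −65.6 percentage points (TPA minus TP, n = 2 each; two-sided exact permutation p = 0.333, the smallest possible). The pooled list cannot be taken as independent evidence for the TP sites, although the labels do not say whether it shares libraries with the later TP lists. Its summits coincide to the base with those of the later TP lists at 36.9% and 30.7% of its peaks, against 8.13% of TP replicate 1 summits found in replicate 2.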

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

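The tests of this part were chosen after the results were seen, except the splits of the BRD9 libraries at the deposited lengths, the BRD9 counts at equal lengths, the BRD9 gene lists and the odds ratios over bins of fold enrichment in TPA, which were computed as fixed beforehand. Peaks on unplaced or random contigs, outside the chromosomes compared, numbered 21 in ARID1A TPA replicate 1 and 55 in TPA replicate 2, against 0 in all other lists. They were singled out as signal in data that no comparison used, and no explanation was tested.

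The ARID1A lists were longer in TPA than in TP, and the authors' values stood apart as well, with a median fold of 18.6 ± 5.29 in TPA and 5.39 ± 0.0301 in TP (SD, n = 2 each) and a median −log10 q of 148 and 56.0 against 13.0 and 12.5, although folds of different lists share no scale. The smallest deposited −log10 q was 2.01 and 2.02 in TP and 2.03 and 2.00 in TPA. These values argue against a looser threshold of the authors in TPA. The ratio of TPA to TP peak numbers was 4.26 at a −log10 q of at least 10. That ratio cannot decide it, since with higher −log10 q values in TPA the filter removes fewer TPA peaks. ARID1A remaining at its TP sites did not account for the added peaks either. Of the 30066 strongest peaks of each TPA list, 15.2% on average lay on TP regions (15.7% and 14.7%), against 82.8% and 84.6% in the TP lists. That share replaced earlier tests whose values had been seen, the share over whole lists, which their length limits (12.7% and 8.31%), and the share in the highest minus the lowest of 4 fold classes (−9.0 and −2.39 percentage points). Scattered background is a candidate explanation that stays open, since 10.9% of the peaks of TPA replicate 1 overlapped replicate 2 (4.19% after random shifts), and the high folds of the TPA peaks were not tested against it. Whether the 14.3% of TP regions called in both TPA lists hold remaining protein or open chromatin tagged without ARID1A cannot be told apart, because no IgG list was analysed, and an effect of ARID1A loss itself on where the antibody signal lies was not tested.

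BRD9 regions called in all libraries of one genotype and none of the other numbered 274 at the deposited lengths, and 661 for the highest other split, which set the 3 longest lists against the 3 shortest and gave 132 at equal lengths, a first test that was dropped because equal lengths must lower it. At equal lengths the genotypes gave 349 regions, 1.27 times the deposited count, and the highest other split 195. These are largely other regions, as 10 of the 205 lost and 12 of the 144 gained ones were in the same class at the deposited lengths. The count at equal lengths therefore cannot say whether unequal lengths were the source of the 274 regions, and length bears on which regions are called. In both cases, as for the gene lists past the threshold (0 for the genotypes and 0 for the highest other split), the 10 splits are too few for a share under 0.05. A difference between genotypes stays open.

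BRD9 regions with ARID1A were kept more often in TPA. Fold rank in 10 bins did not account for the whole difference, since the lowest 95% bound of the odds ratios was 2.70. With bins of −log10 q the odds ratios dropped to between 2.01 and 2.38, with a lowest bound of 1.81. At gene ends alone they were 1.79 to 3.00 over bins of fold, and elsewhere 2.71 to 3.23. Bins hold strength only in part and the measure moved the ratios, so stronger BRD9 peaks stay open as a cause. Region width was not held, although TP regions called in all TPA libraries were wider (median 753.5 bp) than those called in none (487 bp). Easier detection of ARID1A regions in any library stays open: the odds ratio for a TP library left out reached 2.87 (2.57 to 3.21), within reach of the TPA intervals, while the intervals of the other TP libraries (1.71 to 2.23 and 1.96 to 2.69) lay below them. With bins of −log10 q the TP values were 1.25 (1.09 to 1.44), 1.86 (1.65 to 2.10) and 1.46 (1.23 to 1.72), of which the middle one alone meets the TPA intervals. If BRD9 needed a site's ARID1A, regions with ARID1A would be kept less often in TPA. The values ran the other way in 3 of 3 libraries. A dependence masked by easier detection or by stronger peaks cannot be excluded with these lists.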

How the results depend on the processing

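The bins of −log10 q, the comparison inside TP and the splits at equal lengths were chosen after seeing the data. Over all alternatives, 86 values that answer a comparison counted as kept, 24 as moved and 2 as reversed. Kept meant the same direction and side of the threshold, or a move smaller than the spread. Counts of regions have no spread or p-value, so they were not judged by either. Without TP replicate 2, lost ARID1A regions counted as kept (12982 to 19090) and gained BRD9 regions as moved (55 to 86). Of the 205 BRD9 regions lost at equal lengths, also counted as kept, 10 were lost at the deposited lengths. Peak numbers, gene-end shares and the overlap of later ARID1A lists with the pooled list cannot pass the threshold, so that side was fixed. For the named genes and lists, 331 values kept their call and 77 no longer met it. The 331 include all values of the lost and gained genes with a library left out. Those were fixed in advance, since a gene called in all libraries of one genotype and none of the other stays so. Read depth is unknown, so every count of peaks or regions is limited by how deeply each library was sequenced.

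The difference in BRD9 peak number reversed to 1380 without TPA replicate 1 and to 28.2 without TPA replicate 3, and leaving out a library gave −4900 to 1380. These libraries differ in list length (13236 to 25797 peaks in TPA). Lost BRD9 regions ranged from 236 to 1683 and gained ones from 61 to 459 when a library was left out. With calls in at least 2 of 3 libraries they numbered 781 and 655, by the looser rule, and 144 were gained at equal lengths. Gained ARID1A regions numbered 404 at equal lengths, where the TPA lists are shortened, and 3097 to 99524 with a library left out. ARID1A gene lists past the threshold numbered 0 to 4 with a library left out, and the cause was not tested. The share of BRD9 regions with ARID1A was 88.9% at equal lengths, 83.6% with 500 bp windows, 83.0% with both later TP libraries in place of the pooled list, and 82.9% to 85.0% with a library left out, all far above the shifted lists. The cause of these moves was not tested. The retention difference was 12.2 to 22.8 percentage points over the alternatives fixed beforehand and 8.79 inside TP.

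Of the 24 named BRD9 genes, 21 kept the full separation with 3 kb windows and 9 with gene spans. Of the 20 named ARID1A genes, all kept it with the stricter threshold and at equal lengths, 15 with 3 kb windows and 5 with gene spans. The replicate numbers gave no sign of pairing for BRD9. Same-numbered libraries correlated at −0.037 to 0.017 and differently numbered ones at −0.044 to 0.040. With 2 ARID1A libraries per genotype, the values mirror each other (0.0158 for the same number and −0.0158 otherwise), so they cannot decide it. With the replicate block, the exact sign-flip permutation p was 1 for BRD9 peak number (−1164), 0.50 for its gene-end share (1.62) and 0.50 for both ARID1A differences (53201 and −19.2). These tests cannot reach 0.05 with or without the block, so they say nothing about stability. The BRD9 motif search and its alternatives were not run.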

Other observations

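The gene groups of this part were described, and its test was chosen, after the results were seen. The share of genes with both proteins at their ends in TP varied over the gene lists, and the differences were not tested. Of all protein-coding genes, 23.1% had both BRD9 and ARID1A in all TP libraries. Among the highest shares were 78.6% of 28 AP-1 and immediate early genes, 75% of 28 p53 target genes, although Trp53 is deleted in these organoids, 64.7% of 34 cholesterol and lipid synthesis genes and 53.8% of 52 secretory machinery genes. Among the lowest, the lists of gastric cell markers and mucins stood beside lists of other lineages: 3.70% of 27 gastric mucous cell markers, 4.0% of 25 chief and parietal cell markers, 3.13% of 32 enteroendocrine and tuft cell markers and 7.69% of 13 mucins, against 5.88% of 34 neuronal genes chosen as a silent control, 6.25% of 32 immune cell markers, and 0 of 30 intestinal lineage markers, 25 fibroblast and endothelial markers and 39 Hox genes. By contrast, 42.9% of 35 gastric epithelial transcription factors had both. All these shares count gene-end peaks alone. With gene spans and 10 kb, mucous markers such as Cldn18 and Psca had BRD9 in 3 and ARID1A in 2 TP libraries. Others such as Gkn2 and Tff3 had neither in TP, and the lists were not compared with that window.

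At equal list lengths, BRD9 regions gained in TPA lay at gene ends more often than lost ones. Gene ends held 44.4% (36.2 to 53) of the 144 gained and 7.32% (4.15 to 11.8) of the 205 lost regions, against 30.4% of the 8570 regions called in all libraries, with 95% intervals. These are largely other regions than at the deposited lengths: 12 of the gained and 10 of the lost ones were in the same class there. The gene-end share of the equal lists was 2.79 percentage points higher in TPA (n = 3 each; two-sided exact permutation p = 0.10, the smallest possible).

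The pooled ARID1A list of the premalignant samples and the later TP lists may come from the same libraries processed again. The lower share of pooled summits found at the same base in a TP list was 30.7%, against 8.13% between the TP lists, which this hypothesis needs, and the labels do not state it. In the ARID1A TPA lists, the peak names carry replicate numbers 2 and 3 where the labels number the samples 1 and 2.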
